A study of Mus musculus with 6 samples.

How the data were processed

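Total RNA was extracted with TRIzol from small intestine rinsed with cold PBS and sequenced on an Illumina HiSeq instrument, per the labels' protocols and the series' design text, as 3 libraries from mice given LPS and 3 from saline-treated controls. The labels name a standard Illumina library protocol and do not say whether it selected polyadenylated RNA or kept strand, so reads of a gene and of an overlapping antisense gene cannot be told apart here. HISAT2, HTSeq and DESeq2 are named in the submitters' processing notes, without versions, and the genome build and annotation are not given in the sources used here, so no coordinates are given. Gene symbols are used as deposited.

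The authors deposited 1 table of 48587 gene rows by 6 columns, 1 column per sample, matched to the samples by group and replicate number. Its values are not raw counts: the deposited values are a normalised signal, gene counts divided by 1 size factor per library. In each column 100% of the non-zero values were whole multiples of 1 step, within a tolerance of 0.01 reads, so whole reads were recovered for all genes. The factors found from the steps, between 0.662655 and 1.6825, equal the median-ratio factors of the recovered reads, the method of DESeq2. The recovered reads summed to 7078817, 8878032 and 15992114 in control libraries 1 to 3 and 8794397, 16258067 and 17210458 in LPS libraries 1 to 3. A gene with 0 reads in a library can hold up to 3 reads' worth, 1.78 to 4.53 normalised counts depending on the library, and such floors cover counting error only. In 27 rows the symbol had been turned into a date by a spreadsheet program; these rows stayed in the tests and are not named, and 2 symbols stood on 2 rows each.

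The test planned before the data were examined, the edgeR quasi-likelihood test with TMM scaling, assumed raw counts. It was run later on the recovered reads as an alternative. Because the table holds normalised values, the planned replacement was used: limma with an intensity trend on log2(value + 1), on the 22006 rows with a mean normalised count of 1 or more, with group as the sole term and Benjamini-Hochberg adjustment, calling genes at an adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used, and figures were drawn with matplotlib 3.10.9.

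Whether the replicate numbers pair the libraries was checked before the calls of the fits were compared. The deviations of a library's log2 values from its group mean correlated across genes between control and LPS libraries of the same number at 0.647, 0.684 and 0.89. Across numbers 1 and 2 they correlated at 0.652 and 0.631, and between number 3 and the others at -0.734 to -0.805, so the data set number 3 apart from numbers 1 and 2 rather than 3 separate pairs. No label says what a number shares, and the pairing comes from these correlations alone, which do not tell number 1 from number 2. Deviations within a group sum to 0, so the distance of number 3 by itself makes numbers 1 and 2 correlate. Since each same-number correlation was above 0.1, values from limma with the replicate number as a block are given beside every result whose call or count they change. The fold changes are the same in both fits, as the design is balanced, and the fits have 4 and 2 residual degrees of freedom. After the values were seen, log2 values of the immunoglobulin variable segments with a mean of 10 or more were also correlated between all libraries. Within each group no libraries were duplicates: chi-square per degree of freedom was 4.154 and 9.058 between replicates 1 and 2 of control and LPS, and 226.8 to 304.8 against replicate 3.

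The scripts were tested on simulated counts for the 22006 genes with the sizes of these 6 libraries, 100 genes changed 2-fold and 100 changed 4-fold. Libraries of the same replicate number were given the same mean before these changes, and the spread came from the blocked design. The distance between replicate numbers was thus built in, and the recovery cannot show whether the block is right for these data. Without the block, limma, edgeR and limma-voom recovered 0 of each 100, and DESeq2 recovered 6 and 46. With the block limma recovered 84 and 95, edgeR 89 and 96, DESeq2 73 and 85, and limma-voom 87 and 96, and they called 1, 4, 0 and 1 unchanged genes. A planted list was found by camera, and 0 of 20 random lists had p under 0.05. Genes were drawn independently of each other, so the random lists do not test camera where genes are correlated.

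Gene lists (38, with 37 holding at least 5 tested members) were fixed before the data were examined and tested with camera at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. A correlation estimated from the data and fry were alternatives. Genes were named by a rule fixed at the same time: the 10 largest rises and 10 largest falls among genes called without the block, with a mean of 5 CPM (counts scaled to library size) or more and groups that do not overlap, leaving out predicted loci and receptor segments; the 3 members with the smallest adjusted p of each list called by camera and 2 of each list not called; and 15 genes chosen in advance, Tlr4, Cd14, Tnf, Il1b, Il6, Lcn2, Reg3b, Reg3g, Lgr5, Mki67, Muc2, Lyz1, Slc5a1, Apoa4 and Cyp3a11. Fewer members than the rule allows are named for some lists, and some list members are not reported here by name.

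Alternatives fixed before the data were examined were other scalings (recomputed median ratio, upper quartile, library size), no filter and a filter of 1 CPM in 3 libraries, pseudocounts of 0.1 and 10, DESeq2 and limma-voom on the recovered reads, the replicate block, each library left out in turn, and the other list tests. Alternatives added after seeing the data were TMM scaling, edgeR on the recovered reads, the block in edgeR, DESeq2 and limma-voom and with other scalings, 1 term for replicate 3 against replicates 1 and 2, replicates 1 and 2 alone, and each pair left out with the block.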

Results

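RNA sequencing measured transcript levels in the small intestine of wild-type C57BL/6 mice given lipopolysaccharide (LPS), the cell-wall glycolipid of gram-negative bacteria that is sensed through the receptor Tlr4, or saline. LPS was injected into the peritoneal cavity at 2 mg/kg for 24 hours. There were 3 LPS libraries and 3 control libraries, numbered 1 to 3 in each group. The deposited table held 48587 gene rows, 28616 of which had at least 1 read in any library, and 22006 passed the filter on low values. Control libraries 1, 2 and 3 held 7078817, 8878032 and 15992114 gene-assigned reads, and LPS libraries 1, 2 and 3 held 8794397, 16258067 and 17210458. Values below are normalised read counts, each library divided by the authors' size factor, and means are given ± SD with n = 3 libraries per group.

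The libraries split in 2 directions. The first principal component of the log2 values, with 72.3% of the variance, separated both replicate 3 libraries from the other 4, and the second, with 15%, separated LPS from control. Control and LPS libraries of the same number deviated together from their group means, with correlations across genes of 0.647, 0.684 and 0.89 for replicates 1, 2 and 3. Across numbers 1 and 2 the correlations were as high, 0.652 and 0.631. They therefore set replicate 3 apart and do not pair numbers 1 and 2 separately. The immunoglobulin variable segments, whose profile was examined after the values were seen, grouped by treatment instead. Across the 38 segments with a mean of 10 or more normalised counts, log2 values correlated at 0.801 to 0.951 between libraries of 1 group, replicate 3 included, and at -0.0454 to 0.104 between control and LPS libraries. Other genes in the same range of means, 7759 in number, correlated at 0.539 to 0.956 within a group and at 0.462 to 0.914 across groups. The comparison of LPS with control was made without and with the replicate number as a block. In the text below a gene is said to rise or fall where its adjusted p passed 0.05 in limma with the block, and the count without the block stands beside each such count.

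**Figure D1:**
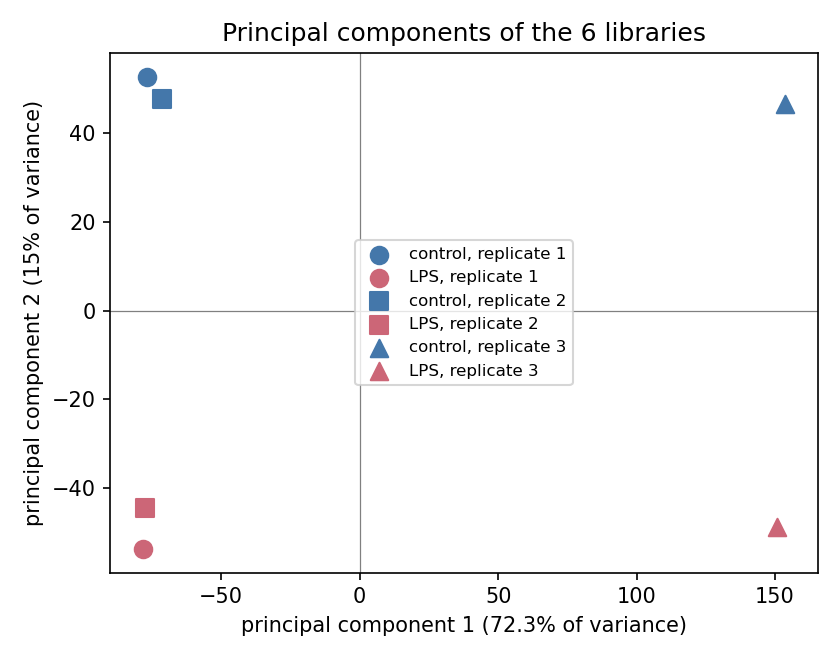
Principal components of log2(normalised count + 1) over the tested genes, with component 1 (72.3% of variance) on the x axis and component 2 (15%) on the y axis, both in arbitrary units. Each point is 1 library, with colour for the group and shape for the replicate number. The replicate 3 libraries lie at 153.74 (control) and 150.79 (LPS) on component 1, and the other 4 lie between -78.41 and -71.49.

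The comparison of LPS with control asked how the intestinal transcriptome responds to systemic endotoxin. With the block, 26 of 32 interferon-stimulated genes, 15 of 25 acute-phase and NF-kB response genes and 11 of 16 antimicrobial defence genes rose, while 1, 6 and 3 fell; without it 2, 3 and 0 rose and none fell. Of genes for sugar, peptide and amino acid absorption, for drug and xenobiotic metabolism, of Paneth cells and of smooth muscle, 21 of 24, 25 of 29, 14 of 17 and 12 of 13 fell, while 1, 3, 1 and 0 rose; without it 1, 2, 1 and 0 fell and none rose. Camera called these 7 lists at a preset inter-gene correlation but none with an estimated correlation (adjusted p = 0.071 to 0.329). The naming rule took genes called without the block, with a mean of 5 CPM or more, and left out receptor segments and predicted loci. The largest rise within this rule was that of Lcn2, the siderophore-binding protein lipocalin 2, from 39.8 ± 34.6 to 12721 ± 13892 normalised counts, 270-fold on the log2(value + 1) scale. The largest fall within the rule was that of Slc28a1, a sodium-coupled nucleoside transporter, from 474 ± 276 to 8.14 ± 3.16, 48.7-fold. Outside the rule, and picked after the values were seen, the acute-phase genes Saa3 and Saa1 had log2 fold changes of 7.44 and 5.33, called with the block alone (adjusted p = 6.47e-17 and 8.38e-16), and the immunoglobulin segment Ighv1-15 had one of -5.64. The segment profile followed the groups, so the fall of Ighv1-15 cannot be told apart from a difference between the source animals.

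Without the block, limma called 43 genes at an adjusted p under 0.05, 24 higher and 19 lower in LPS, all 43 changed by 2-fold or more. With the replicate number as a block it called 6040 genes, 27.4% of those tested, with 2729 higher and 3311 lower. Of these, 792 rose and 740 fell by 2-fold or more. All 43 were among the 6040. Of the 6040, 5980 had the same sign in 3 of 3 pairs of libraries, an agreement that the blocked fit itself selects for. The direction split depended on the scaling: after scaling by library size, the blocked fit called 3815 genes higher and 2414 lower. In 2929 genes, 13.3%, the LPS and control libraries did not overlap. Chance gives 10% with 3 against 3 only where the libraries are exchangeable. The distance of replicate 3 in both groups makes overlap more likely, so 10% is not the share to expect here, and that share was not estimated. Within replicates 1 and 2 alone, fitted without a block, 3998 genes were called, 1655 higher and 2343 lower. In the unblocked fit, leaving out control library 1 or 2 or LPS library 1 or 2 ended all calls, with 900 to 1063 genes at an unadjusted p under 0.05, and 17 and 8 genes were left without control library 3 and LPS library 3.

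Within the rule, the genes with the largest rise also included Slc6a14, an amino acid transporter (4.89 ± 1.47 to 132 ± 3.68, 23.1-fold), the acute-phase serpin Serpina3n (79.4 ± 12.1 to 1659 ± 811, 19.4-fold) and the pregnancy-specific glycoprotein Psg18 (5.48 ± 0.604 to 125 ± 22.4, 19.3-fold). The interferon-induced GTPase Gbp2 rose from 66.0 ± 3.24 to 1226 ± 261, a log2 fold change of 4.18 with an SE of 0.24 (adjusted p = 0.00821). Beside these stood 2 glycosyltransferases, B3galt5 (27.6 ± 6.38 to 472 ± 43.7, 16.8-fold) and the fucosyltransferase Fut2 (34.1 ± 11.6 to 466 ± 20.4, 13.8-fold). The metalloreductase Steap4 rose 16.2-fold, Mfi2, which encodes the iron-binding melanotransferrin, 16.1-fold, and Myot, a Z-disc protein of striated muscle, 13.6-fold. The log2 fold change of Lcn2 was 7.47, 8.27 and 8.49 in pairs 1, 2 and 3, with an adjusted p = 0.045 without the block. The adjusted p of the other 9 lay between 0.00821 and 0.045 without the block.

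Among the largest falls within the rule were both sodium-glucose cotransporter relatives Slc5a4a (368 ± 41.9 to 13.9 ± 0.59, a log2 fold change of -4.63 with an SE of 0.25, adjusted p = 0.00821) and Slc5a4b (17.5-fold), which are close relatives and can share reads. Fam151a fell from 821 ± 41.8 to 37.1 ± 7.0 (21.8-fold). The brush-border enzyme lactase, Lct, fell from 11142 ± 1783 to 1068 ± 132 (10.4-fold), and the membrane peptidase Mme from 1940 ± 361 to 187 ± 31.2 (10.3-fold). The drug-metabolising cytochrome P450 genes Cyp3a11 (4295 ± 690 to 333 ± 108), Cyp2c55 and Cyp2c68 fell 13.2-fold, 13.2-fold and 9.19-fold, and the glucuronosyltransferase Ugt2a3 fell 7.93-fold. All 10 passed without the block, at an adjusted p between 0.00821 and 0.049.

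**Figure D2:**
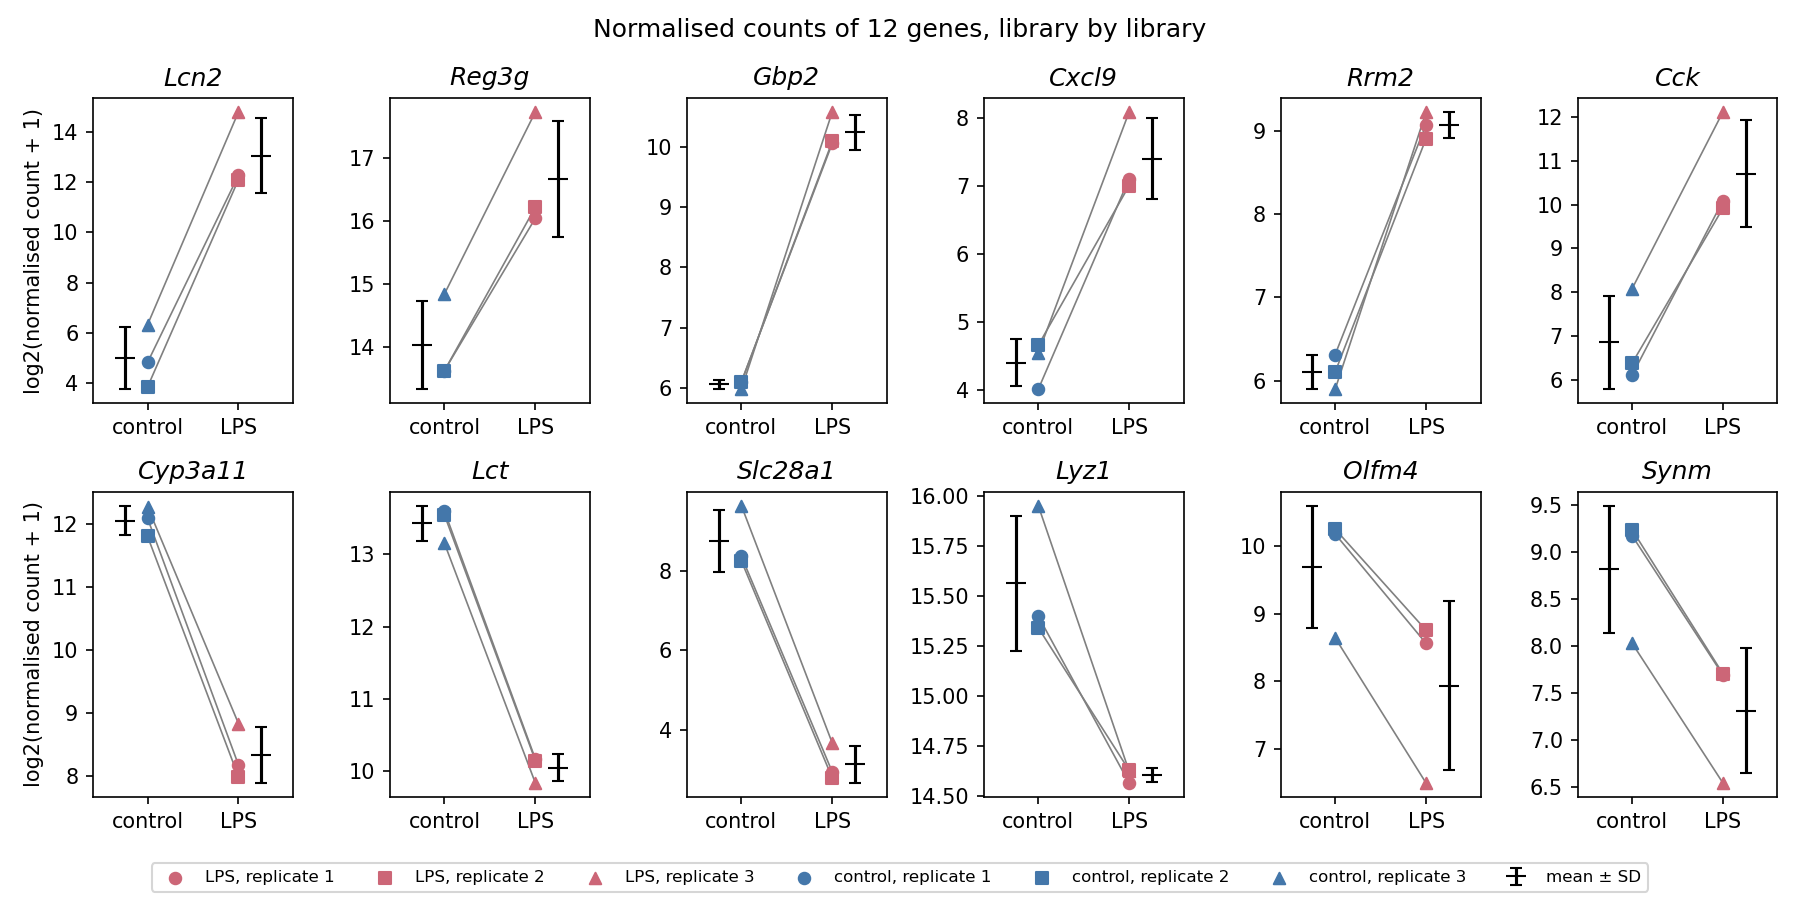
Normalised counts of 12 named genes on a log2(value + 1) scale (y axis, a separate range for each gene that does not start at 0) in control and LPS libraries (x axis). Points are single libraries, grey lines join libraries of the same replicate number, and bars give the mean ± SD of the 3 log2 values. In each panel the 3 lines run in 1 direction, while the replicate 3 points of Lcn2, Reg3g, Cck, Olfm4 and Synm lie apart from the others of their group.

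The gene lists below were fixed before the data were examined, and camera, which compares a list with all other genes, called 20 of the 37 lists with enough tested members at its preset inter-gene correlation. None of the 20 held with a correlation estimated from the residuals, whose adjusted p stands with each list. Without the block that version rests on 4 residual degrees of freedom, and its residuals hold the distance of replicate 3. With the block, which takes out that distance but leaves 2 residual degrees of freedom, it also called 0 lists, with camera adjusted p of 0.263 or more. Both versions have little power here, and their lack of calls does not decide for or against a list. The small camera p-values below rest on the preset correlation of 0.01, which these data do not establish. List members given in brackets behind a count of 5 or fewer were picked after their values were seen, unless they are also named by the rule. Members of multigene families, such as the alpha-defensins, the Reg3 genes, the lysozymes, the Cyp2c genes, the H2-Q genes and Slc5a4a with Slc5a4b, can share reads, so values of single members are uncertain.

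Interferon-stimulated genes rose as a group: of 32 tested, 26 rose and 1 (Ddx58) fell with the block, and 2 rose without it. Their median log2 fold change was 1.01, with 0.927, 0.911 and 1.05 in pairs 1, 2 and 3 (adjusted p = 3e-18; adjusted p = 0.071 with an estimated correlation). Gbp3, another guanylate-binding GTPase, rose from 34.1 ± 11.03 to 294 ± 30.5, and Ifit3 from 44.8 ± 14.7 to 258 ± 143, the latter called with the block alone (adjusted p = 5.03e-10, against 0.155 without). Of 25 acute-phase and NF-kB response genes, 15 rose and 6 fell with the block, and 3 rose without it (median 1.09, adjusted p = 1.6e-07; adjusted p = 0.155 with an estimated correlation). The 3 were Lcn2, Serpina3n and Steap4. The 6 that fell, named after their values were seen, were Bcl3, Ptgs2, Nfkb2, Socs3, Tnfaip3 and Relb. Their log2 fold changes ran from -1.41 to -0.42, so the list did not move in 1 direction. Tnf rose from 5.16 ± 3.91 to 13.4 ± 0.9 with the block (adjusted p = 0.0166) but was not called within replicates 1 and 2 alone (adjusted p = 0.188). Il1b stood at 6.48 ± 1.599 and 5.28 ± 2.79 and was not called. Il6 had 0 reads in all 6 libraries, which allows up to 1.78 to 4.53 normalised counts, depending on the library. Of 21 chemokines, 12 rose and 4 (Ccl25, Cxcl16, Ccl6 and Cxcl14) fell with the block, and none was called without it (median 0.964, adjusted p = 5.21e-05; adjusted p = 0.333 with an estimated correlation). Cxcl9, an interferon-induced T cell attractant, rose from 20.5 ± 4.80 to 178 ± 80.1, and the monocyte attractant Ccl2 from 1.52 ± 1.89, on 4 reads, to 51.2 ± 17.7. Cxcl5 had 0 control reads and was at least 4.31-fold higher in LPS by the group mean, against a floor of 3 reads over the control group. That mean rests on 4, 8 and 7 reads in LPS libraries 1, 2 and 3. Of 17 genes of MHC class I presentation, 12 rose with the block and none without it (median 0.429, adjusted p = 0.00714; adjusted p = 0.599 with an estimated correlation). Tap1, the peptide transporter subunit, rose from 711 ± 212 to 1306 ± 396, and the immunoproteasome subunit Psmb8 from 671 ± 400 to 1297 ± 741. Genes of endotoxin sensing went both ways: 5 of 21 rose (Cd14, Tlr2, Irak3, Traf6 and Irak1), 3 fell (Irak2, Tollip and Ticam1) and none was called without the block (median 0.167, adjusted p = 0.156). Cd14, the LPS co-receptor, rose from 104 ± 48.6 to 255 ± 142, while Tlr4 itself stood at 15.5 ± 14.2 and 21.5 ± 16.7 and was not called. Adjusted over the list alone, the counts higher and lower with the block were 26 and 1, 15 and 7, 12 and 5, 12 and 0, and 6 and 3 for these 5 lists in order, and without it 15, 10, 6, 0 and 0 rose and none fell.

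With the block, 5 of 10 neutrophil markers and 9 of 18 macrophage and monocyte markers rose, and 10 of 15 B cell and plasma cell markers fell, none of them without the block. Of 10 neutrophil markers, 5 rose (Cd177, Ly6g, S100a9, S100a8 and Ngp) and Mmp9 fell with the block (median 0.88, adjusted p = 0.00211; adjusted p = 0.329 with an estimated correlation and 0.0572 within replicates 1 and 2 alone). Cd177 rose from 68.4 ± 19.3 to 150 ± 29.7, and Ly6g, with 0 control reads, was at least 17.5-fold higher in LPS by the group mean. That mean rests on 9, 23 and 45 reads in LPS libraries 1, 2 and 3, so library 3 weighs most in it. Of 18 macrophage and monocyte markers, 9 rose and 2 (Csf1r and Cx3cr1) fell (median 0.385, adjusted p = 0.0225; adjusted p = 0.18 with an estimated correlation), among them the scavenger receptor Msr1, from 17.1 ± 5.19 to 51.6 ± 13.4, and the antibody receptor Fcgr1, from 7.26 ± 5.85 to 35.1 ± 11.7. Of 15 B cell and plasma cell markers 10 fell and none rose (median -0.83, adjusted p = 1.76e-07; adjusted p = 0.175 with an estimated correlation). Jchain, which joins IgA and IgM polymers, fell from 1085 ± 142 to 512 ± 87.3, and Sdc1, a plasma cell marker that epithelial cells express too, from 2199 ± 181 to 1168 ± 110. Of 19 T cell and intraepithelial lymphocyte markers, 2 rose (Ccl5 and Gzmb) and 6 fell, and the list was called without the block (median -0.445, adjusted p = 0.0173; adjusted p = 0.425 with an estimated correlation) and not with it (adjusted p = 0.187). Within replicates 1 and 2 alone, 1 of its genes rose and 1 fell, and after scaling by library size 2 rose and 2 fell with the block. Of 12 genes of MHC class II presentation, 2 rose (Cd74 and H2-DMb1) and 5 fell (Ciita, Ifi30, H2-Ob, H2-Ab1 and H2-Eb1), and the list was not called (median -0.212, adjusted p = 0.274). After scaling by library size 3 rose and 3 fell. Ciita, the transactivator of these genes, fell from 198 ± 93.0 to 87.4 ± 47.3. In these 5 lists no gene was called without the block. With p-values adjusted over the list alone, the counts higher and lower were 5 and 1, 10 and 2, 0 and 12, 2 and 7, and 2 and 6 with the block, and 4 and 1, 3 and 0, 0 and 2, 0 and 0, and 0 and 0 without it.

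Most antimicrobial defence genes rose, while most Paneth cell markers fell. The RNA came from whole intestine, so the cells behind these changes are not resolved. Of 16 antimicrobial defence genes 11 rose and 3 (Nos2, Reg3a and Pigr) fell with the block, and none was called without it (median 1.26, with 1.05, 1.48 and 1.62 in pairs 1, 2 and 3, adjusted p = 4.32e-06; adjusted p = 0.329 with an estimated correlation). The bactericidal lectins Reg3g and Reg3b rose from 18163 ± 9639 to 120245 ± 84035 and from 43999 ± 24011 to 216032 ± 142778. The corresponding log2 fold changes were 2.42, 2.60 and 2.89 for Reg3g and 2.07, 2.22 and 2.41 for Reg3b in pairs 1, 2 and 3. Lactoferrin, Ltf, which neutrophils also make, and whose rise stood beside that of the neutrophil markers Ly6g, S100a9, S100a8 and Ngp, rose from 5.58 ± 1.96 to 53.3 ± 28.4. Retnlb, with 0 control reads, was at least 5.34-fold higher by the group mean, on 4, 7 and 12 reads in LPS libraries 1, 2 and 3. Of 17 Paneth cell markers 14 fell and 1 (Mmp7) rose with the block, and 1, Mptx2, fell without it (median -0.914, with -0.833, -0.707 and -1.09 in pairs 1, 2 and 3, adjusted p = 3.77e-07; adjusted p = 0.329 with an estimated correlation). Mptx2 fell from 872 ± 157 to 116 ± 26.8, the lectin Itln1 from 21426 ± 4293 to 8580 ± 830, the ribonuclease Ang4 from 2440 ± 862 to 837 ± 147 and lysozyme, Lyz1, from 49334 ± 12138 to 24941 ± 604. Goblet cell markers went both ways, with 3 of 14 higher (Creb3l1, Ccl9 and Muc3) and 5 lower (Clca1, Fcgbp, Agr2, Zg16 and Atoh1), and were not called as a list (median -0.103, adjusted p = 0.693). After scaling by library size 5 rose and 4 fell. The secreted mucin Muc2 stood at 54154 ± 1536 and 51834 ± 3902 and was not called. Of 12 tuft cell markers 1 rose (Ptgs1) and 3 fell (Trpm5, Avil and Ltc4s), and the list, whose median of -0.0444 turned positive after scaling by library size, was not called (adjusted p = 0.522). Of 17 enteroendocrine markers 5 rose (Cck, Tac1, Gcg, Pyy and Tph1) and 2 fell (Gip and Sct), and the list was not called (adjusted p = 0.253). Its median of -0.00293 and its mean of 0.282 differed in sign, camera gave the direction of the mean, and the median turned positive with TMM and library size scaling. No goblet, tuft or enteroendocrine marker was called without the block. Cck, which encodes cholecystokinin, rose from 140 ± 112 to 2162 ± 1967 (14.4-fold, with log2 fold changes of 3.98, 3.54 and 4.04 in pairs 1, 2 and 3). Adjusted over the list alone, the counts higher and lower with the block were 11 and 3, 1 and 14, 5 and 6, 1 and 3, and 5 and 2 for these 5 lists in order, and without it 6 and 0, 0 and 3, 0 and 0, 0 and 0, and 1 and 0.

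Of proliferation genes more rose than fell, while stem cell markers changed in both directions. Of 21 proliferation genes 12 rose and none fell with the block, and 1 rose without it (median 0.295, adjusted p = 1e-04; adjusted p = 0.124 with an estimated correlation). That gene was Rrm2, a ribonucleotide reductase subunit, which rose from 68.2 ± 9.99 to 540 ± 59.3. The others changed less: Mki67 rose from 1441 ± 800 to 2023 ± 1068 (log2 fold change 0.51, but -0.0993 in the unblocked fit without control library 3) and Top2a from 506 ± 134 to 725 ± 188. In pairs 1, 2 and 3 the log2 fold change of Mki67 was 0.398, 0.562 and 0.575. Of 14 stem cell markers 3 rose (Prom1, Ephb2 and Smoc2) and 6 fell with the block, none was called without it, and the list was not called (median -0.298, with -0.176, -0.157 and -0.796 in pairs 1, 2 and 3, adjusted p = 0.0932). Lgr5, the receptor that marks crypt-base stem cells, fell from 129 ± 61.7 to 64.5 ± 41.7, Olfm4 from 924 ± 456 to 299 ± 184, and the Wnt target Axin2 from 923 ± 230 to 343 ± 162. With p-values adjusted over the list alone, 14 and 0 proliferation genes and 3 and 7 stem cell markers were higher and lower with the block, and 1 and 0, and 0 and 0, without it.

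Most genes for the absorption of sugars, peptides and amino acids and for drug metabolism fell. Of 24 genes for sugar, peptide and amino acid absorption 21 fell and 1, the fructose transporter Slc2a5, rose with the block, and 1, Lct, fell without it (median -0.571, with -0.637, -0.609 and -0.39 in pairs 1, 2 and 3, adjusted p = 1.17e-08; adjusted p = 0.071 with an estimated correlation). Trehalase, Treh, fell from 2547 ± 1042 to 467 ± 242 and the proline transporter Slc6a20a from 4221 ± 477 to 1266 ± 216. The main glucose cotransporter Slc5a1 fell little, from 27604 ± 1262 to 22222 ± 581 (adjusted p = 0.00312 with the block). Of 29 genes of drug and xenobiotic metabolism 25 fell and 3 rose (Por, Nr1i2 and Cyp3a13) with the block, and 2, Cyp3a11 and Ugt2a3, fell without it (median -1.02, adjusted p = 2.72e-20; adjusted p = 0.16 with an estimated correlation). The epoxygenase Cyp2j6 fell from 1419 ± 121 to 388 ± 64.2 (adjusted p = 0.051 without the block and 2.08e-12 with it). Of 21 genes of tight junctions and epithelial adhesion 13 fell and 1 (Cldn2) rose with the block, and none was called without it (median -0.283, adjusted p = 0.00665; adjusted p = 0.16 with an estimated correlation). Cldn4 fell from 2895 ± 1470 to 904 ± 432, Cldn15 from 4758 ± 1394 to 2865 ± 911, and Mylk, a myosin kinase that smooth muscle expresses too, from 4185 ± 294 to 2209 ± 233. Adjusted over the list alone, the counts higher and lower were 1 and 21, 3 and 26, and 2 and 14 with the block, and 1 and 5, 0 and 16, and 0 and 0 without it.

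Lists of lipid metabolism differed in their counts, and differences between lists were not tested. Of 21 fatty acid oxidation genes and PPAR alpha targets 11 rose and 6 fell with the block (median 0.218, adjusted p = 0.0164; adjusted p = 0.329 with an estimated correlation). Pdk4, which restrains pyruvate oxidation, rose from 340 ± 65.2 to 1177 ± 139, and the acyl-CoA thioesterase Acot2 from 245 ± 46.4 to 552 ± 64.5. Of 19 cholesterol synthesis genes 11 fell and none rose (median -0.271, adjusted p = 0.00298; adjusted p = 0.18 with an estimated correlation), with Dhcr7 falling from 822 ± 318 to 527 ± 158. Lipid absorption and lipoprotein genes went both ways, with 5 of 23 higher (Plin2, Fabp1, Apoa4, Dgat2 and Abcg8) and 10 lower, and the list was not called (adjusted p = 0.693). Its median of 0.0164 and mean of -0.0289 differed in sign, and the median turned negative with upper quartile scaling, while after scaling by library size 10 of its genes rose and 7 fell. Apoa4, an apolipoprotein of chylomicrons, rose from 56085 ± 33039 to 141239 ± 96469, and the cholesterol transporter Npc1l1 fell from 13941 ± 4045 to 8054 ± 2139. Of 11 bile acid handling genes 4 rose (Fgf15, Nr1h4, Slc51b and Nr0b2) and 3 fell (Abcc2, Slc51a and Cyp27a1), and the list was not called (median 0.133, adjusted p = 0.253). Fgf15, the ileal hormone that represses hepatic bile acid synthesis, rose from 141 ± 58.9 to 433 ± 238, and its activator Nr1h4 from 2006 ± 284 to 3517 ± 875. Oxidative phosphorylation genes were not called without the block (median -0.18, adjusted p = 0.407) and were called lower with it (adjusted p = 0.00482; adjusted p = 0.54 with an estimated correlation), where 12 of 25 fell and 1 (Cycs) rose. After scaling by library size 3 fell and 3 rose with the block. No gene of these 5 lists was called without the block. With p-values adjusted over the list alone, the counts higher and lower with the block were 14 and 6, 0 and 12, 7 and 10, 4 and 3, and 1 and 15, and without it 2 fatty acid oxidation genes rose.

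Of 5 lists related to stress, rhythm and cell death, 3 were called. Of 18 unfolded protein response genes 11 rose and 1, Atf3, fell with the block (median 0.277, adjusted p = 0.00714; adjusted p = 0.553 with an estimated correlation). Chac1, a glutathione-degrading enzyme, rose from 82.7 ± 16.9 to 427 ± 129, and asparagine synthetase, Asns, from 292 ± 77.0 to 943 ± 324. Of 15 glucocorticoid-responsive genes 9 rose and 4 (Mt1, Nr3c1, Mt2 and Cdkn1a) fell (median 0.435, adjusted p = 0.00117; adjusted p = 0.18 with an estimated correlation). Hsd11b2, which inactivates corticosterone, rose from 296 ± 159 to 968 ± 473, Cyp11b1, the last enzyme of corticosterone synthesis, from 4.13 ± 3.82, on 9 reads, to 30.7 ± 17.6, and the receptor co-chaperone Fkbp5 from 1854 ± 435 to 3752 ± 944. Of 15 immediate early genes 8 fell and 1 (Ier3) rose (median -0.299, adjusted p = 0.00166; adjusted p = 0.329 with an estimated correlation), among them Fos, from 1091 ± 223 to 359 ± 29.9, and Btg2, from 1310 ± 68.4 to 723 ± 82.6. Of 16 circadian clock genes 7 rose and 5 fell (Nr1d1, Npas2, Arntl, Dbp and Clock), and the list was not called (median 0.093, adjusted p = 0.439). Of 20 cell death and inflammasome genes 7 rose and 5 fell, among them Gsdmc4, Gsdmc2, Tnfrsf10b and Ripk1. That list was not called (adjusted p = 0.894), and its median of -0.05 turned positive after scaling by library size. The gasdermin Gsdmc4 fell from 53.4 ± 6.06 to 11.04 ± 4.57. No gene of these 5 lists was called without the block. Adjusted over the list alone, the counts higher and lower were 13 and 2, 10 and 4, 1 and 9, 7 and 5, and 7 and 5 with the block, and 2 and 1, 0 and 0, 0 and 3, 0 and 0, and 2 and 3 without it.

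Of the lists for other cell types in the gut wall, the smooth muscle list was called. Of 13 smooth muscle markers 12 fell and none rose with the block, none without it (median -0.867, with -0.774, -0.927 and -0.786 in pairs 1, 2 and 3, adjusted p = 2.01e-05; adjusted p = 0.16 with an estimated correlation). The intermediate filament protein Synm fell from 481 ± 191 to 169 ± 66.2, calponin, Cnn1, from 932 ± 542 to 366 ± 257, and the myosin heavy chain Myh11 from 4913 ± 881 to 3072 ± 421. The fibroblast list was not called (adjusted p = 0.693), with 3 of 15 higher (Dcn, Pdgfrb and Pdpn) and 5 lower (Fn1, Postn, Col1a1, Col3a1 and Fbn1). Its median of -0.0647 went against the direction camera gave and turned positive after scaling by library size, where 4 rose and 4 fell. Endothelial markers (4 of 14 higher, Tie1, Lyve1, Kdr and Emcn, and 2 lower, Vwf and Plvap, median 0.246, adjusted p = 0.253) and enteric neuron and glia markers (1 of 14 higher, median 0.226, adjusted p = 0.407) were not called either. The 1 was the receptor tyrosine kinase Ret, which rose from 141 ± 8.36 to 567 ± 131. Of 9 adipocyte markers 4 rose (Lep, Plin4, Cidec and Fabp4) and 2 fell (Car3 and Plin1), and the list was not called (median 0.304, adjusted p = 0.407). Lep, which encodes leptin, had 0 control reads, stood at 26.1 ± 2.31 in LPS, at least 22.3-fold higher, and was called without the block too (adjusted p = 0.017). Of 5 erythroid markers 1 fell (Hbb-bs, with a log2 fold change of -0.51, or 0.0109 in the unblocked fit without control library 3), and the list was not called (median -0.232, adjusted p = 0.722). Of 7 proximal small intestine markers 2 rose (Slc40a1 and Ttr) and 3 fell (Gata4, Ada and Cybrd1, median -0.731, adjusted p = 0.364). Of 15 pancreatic acinar genes 4 passed the filter, too few for the list test, and 1 (Pnliprp1) fell. Lep aside, no gene of these 8 lists was called without the block. With p-values adjusted over the list alone, the counts higher and lower were 0 and 12, 3 and 6, 4 and 2, 1 and 0, 4 and 2, 0 and 1, 2 and 3, and 0 and 1 with the block, and without it 1 neuron marker rose, 1 adipocyte marker rose and 1 fell, and 1 proximal marker fell. The medians of the neutrophil, chemokine, antimicrobial and adipocyte lists were the same with their members at 0 control reads set to the floor.

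**Figure D3:**
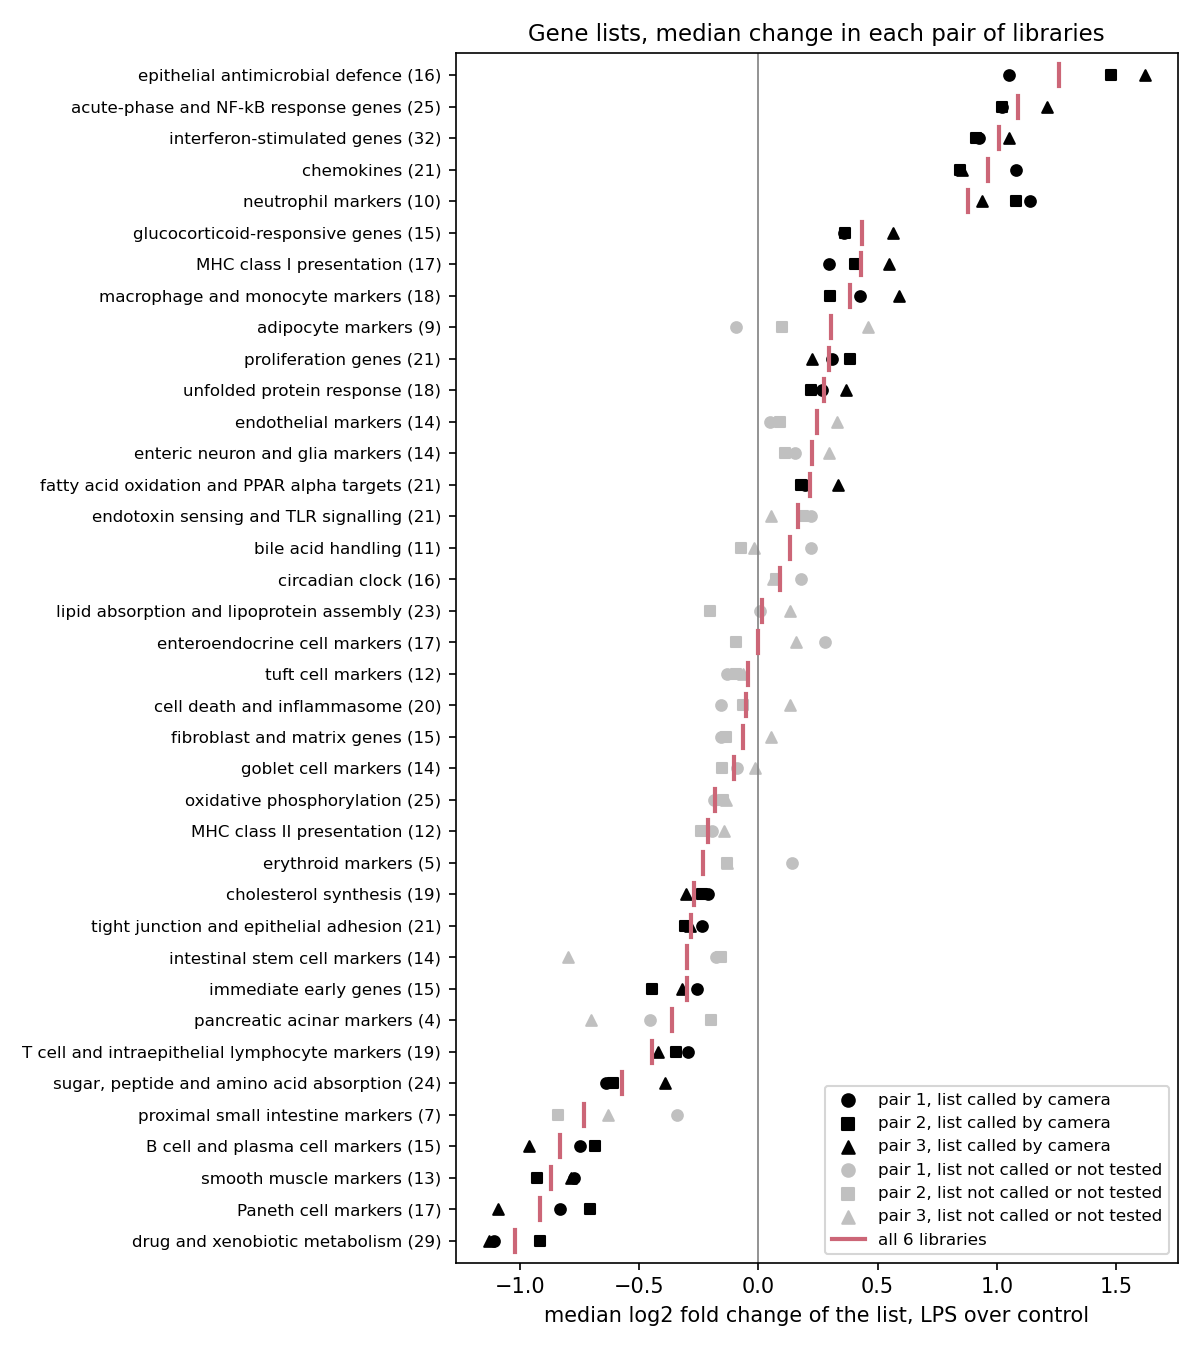
Median log2 fold change of LPS over control (x axis) for each of the 38 gene lists (y axis, with the number of tested genes in brackets). Points give the median within each pair of libraries of 1 replicate number, black where camera called the list and grey otherwise, and the red bar gives the median over all 6 libraries. In each of the 20 called lists the 3 pairs lie on 1 side of 0, from drug and xenobiotic metabolism at -1.02 to epithelial antimicrobial defence at 1.26.

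Tests were two-sided. The blocked fit has 2 residual degrees of freedom, so its small p-values rest on a spread shared across genes. The labels do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical, and need not cover the spread between animals.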

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

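The replicate block in limma and camera on the deposited values was fixed before the data were examined, while the block with other tools, scalings, fry or an estimated correlation, TMM scaling, edgeR, the term for replicate 3, replicates 1 and 2 alone and the pairs left out were chosen after the data were seen. Without the block limma called 43 genes, 24 higher and 19 lower, and the count stayed between 33 and 60 with recomputed median-ratio, upper quartile or TMM scaling, no filter, the stricter filter (60, with 31 lower), pseudocounts of 0.1 and 10, edgeR and limma-voom. Scaling by library size gave 79 genes, 44 higher and 35 lower, all 79 changed 2-fold or more, and shared 35 of the 43. DESeq2 gave 371, 170 higher and 201 lower, 338 of them 2-fold. The replicate block moved the count most: limma called 6040 genes (2729 higher, 3311 lower, 1532 by 2-fold or more), edgeR 6739 (3449, 3290 and 1189), DESeq2 3899 (1522, 2377 and 995) and limma-voom 6478 (3261, 3217 and 1176). A single term for replicate 3 gave 5737 (2580, 3157 and 1490), and replicates 1 and 2 alone gave 3998 (1655, 2343 and 1180). With the block, TMM scaling gave 6111 (3047, 3064 and 1550), upper quartile scaling 6178 (2507, 3671 and 1560) and library size scaling 6229 (3815, 2414 and 1575), so the share of calls that were higher ran from 40.6% to 61.2%. Library size scaling put the median log2 fold change of all genes at 0.113, against 0.0166 with the authors' factors. All 43 genes were shared with each of these blocked fits and with replicates 1 and 2 alone. Leaving out 1 library, or 1 pair with the block, gave 0 to 5768 genes called, 0 to 2553 higher, 0 to 3215 lower and 0 to 1483 by 2-fold or more. In limma without the block it was 0 without control or LPS library 1 or 2, where 900 to 1063 genes had an unadjusted p under 0.05, 17 without control library 3 and 8 without LPS library 3. With the block and pair 1, 2 or 3 left out it was 4861, 4627 and 5768. Fewer libraries leave fewer degrees of freedom, and where the block raised the count it took out the distance between replicate 3 and the others. The cause of the other changes was not tested.

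Camera called 20 lists, 15 to 21 under other scalings, filters and pseudocounts, with the replicate block (20) and with libraries or pairs left out. It called 0 with an estimated correlation, with or without the block, and fry called 7 without the block and 24 with it. The 120 named genes gave 3430 values under the alternatives, of which 2202 kept direction and side of the threshold and 12, in 6 genes, reversed direction. With the block 89 of the 120 became called and 31 were on the same side, and beyond these, the gene and list counts given with it and the lists of T cells and oxidative phosphorylation it changed no other call. None of the reversed values passed the test, although Hbb-bs and Mki67 were called, lower and higher, with the block and all 6 libraries. Hbb-bs was at 0.0109 without control library 3 (range over left-out libraries and pairs -1.13 to 0.0109, against -0.509 with all). Alas2 was at -0.188 without control library 3, -0.100 without LPS library 1 and -0.0544 without LPS library 2 (-0.188 to 0.756, against 0.2), and Tlr4 at -0.522, -0.128 and -0.0137 without the same libraries (-0.522 to 1.52, against 0.46). Il1b was at 0.0747 without LPS library 1 and 0.183 with the block and pair 1 left out (-0.66 to 0.183, against -0.345), and Mki67 at -0.0993 without control library 3 (-0.0993 to 1.09, against 0.512). Muc2 was at 0.0374 with library size scaling, with and without the block, against -0.0654. Leaving out 1 library of the unblocked fit unbalances replicate 3 between the groups, so its distance from the others enters those fold changes. Beyond that, why these values reversed was not tested. Depth limits the lowest genes: 0 reads allow up to 4.53 normalised counts in control library 1, the shallowest, and the fold changes of Cxcl5, Retnlb, Ly6g, Lep and Csf3 are bounds. These bounds allow for counting error in the controls and not in the LPS libraries.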

Other observations

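The gene families below were chosen by symbol after the table of all genes was seen, as were the tests of RNA selection, depth, muscle wall, dilution and variable segments. The tests of another gut stretch, Paneth cells and splits were set before their results were seen. Counts of genes that rose or fell are from limma with the replicate block, with the count without it after each. Since the families were picked from the values, no p-value is given for them, and their counts describe these libraries. Of 17 guanylate-binding proteins and immunity-related GTPases, interferon-induced defenders against intracellular microbes, 15 rose and 1 fell, against 4 and 0 without the block (median log2 fold change 2.29), among them Gbp5, from 13.7 ± 5.39 to 189 ± 49.0, and Iigp1, from 16.8 ± 3.72 to 138 ± 8.70. Of 22 Ly6, Lypd and Gml genes, which encode small surface proteins, 13 rose and none fell, against 0 and 0 (median 1.38). Lypd8, which keeps flagellated bacteria from the epithelium, rose from 26204 ± 19411 to 146642 ± 130175, and Ly6a from 147 ± 116 to 2107 ± 2085, with SDs set by the distance of replicate 3. Of 10 serpins of clade A3, 9 rose and none fell, against 3 and 0 (median 2.58). Of 6 interferon-induced transmembrane protein genes 3 rose, Ifitm1, Ifitm3 and Ifitm2, and none fell, against 0 and 0 (median 0.793). Some members, such as Gbp2 and Gbp3, are also in the gene lists fixed in advance, members can share reads, and the directions held under TMM, upper quartile and library size scaling.

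In families of detoxification and in the alpha-defensins more genes fell than rose with the block. Of 62 cytochrome P450 genes 29 fell and 11 rose, against 3 and 0 without the block (median -0.458), including Cyp2b10, from 1499 ± 811 to 162 ± 107, and Cyp4f14, from 20007 ± 4638 to 7446 ± 2192. Of 15 carboxylesterases 8 fell and 1 rose, against 0 and 0 (median -0.572), with Ces2a falling from 11120 ± 4181 to 2138 ± 1055. Of 12 UDP-glucuronosyltransferases 6 fell and none rose, against 1 and 0 (median -0.537). Of 20 alpha-defensins 15 fell and none rose, against 0 and 0 (median -0.893). The medians of these 4 families were negative under each scaling. Among 297 solute carriers 66 rose and 80 fell, against 2 and 4, among 26 glycosyltransferases 5 rose and 4 fell, against 2 and 0, and both medians changed sign with the scaling. None of 4 tested T cell receptor variable segments was called in either fit. Single genes called without the block, chosen after their values were seen, included glucose-6-phosphatase, G6pc, which rose from 858 ± 115 to 8632 ± 1772 (adjusted p = 0.0144), and the alkaline sphingomyelinase Enpp7 and the phospholipase Plb1, which fell from 13447 ± 1011 to 3145 ± 252 and from 11070 ± 325 to 2249 ± 298. Csf3, the granulocyte growth factor, had 0 control reads and was at least 13.2-fold higher in LPS.

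The variable segments of immunoglobulins had different profiles in the groups. Of 117 segments 36 fell and 10 rose, against 2 and 0 without the block (median -0.552), and Ighv1-15 fell from 121 ± 40.6 to 1.42 ± 0.729. The lowest correlation between libraries of 1 group, 0.801, lay 0.697 above the highest between the groups, 0.104, while other genes correlated more strongly between control and LPS library 3 (0.914) than between control libraries 1 and 3 (0.539). A candidate explanation is that the 3 libraries of a group were made from the same RNA, animal or pool. A change of segment use by LPS that is common to separate animals would give the same difference of 0.697 only if untreated animals also shared 1 profile. The control libraries correlated with each other at 0.886 to 0.951, which LPS cannot have caused. Whether separate untreated mice share such a profile was not tested. These explanations cannot be told apart here because the profile follows the groups. If the source was shared, differences between animals would be confounded with LPS in any gene.

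Both replicate 3 libraries stood apart from the other 4. Replication-dependent histone genes, whose transcripts lack a poly(A) tail, were lower in them by a median log2 difference of -5.58 in control and -5.86 in LPS (62 genes), and 7SK, 7SL and similar RNAs took 3.63% to 4.36% of reads in replicates 1 and 2 and 0.00312% to 0.00313% in replicate 3, consistent with a library type that selects poly(A) RNA. Depth is argued against: at equal numbers of reads, each library of replicates 1 and 2 had at least 3595 more genes detected than either replicate 3 library. Whether another stretch of gut adds to the distance stays open, since the proximal and bile acid lists differed by 1.15 but moved the same way (0.153 and 1.3 relative to all genes).

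Smooth muscle markers fell in all 3 pairs, with medians of -0.774, -0.927 and -0.786 (median over all libraries -0.867, bootstrap interval over genes -1.28 to -0.562). Less muscle wall in the LPS samples is argued against by enteric neuron and glia markers, whose median of 0.226 (-0.192 to 0.383) lay 1.09 above that of smooth muscle. Dilution of all non-epithelial cells is argued against by endothelial and fibroblast medians of 0.246 and -0.0647, at least 0.802 above that of smooth muscle. A lower level of contractile transcripts in LPS may remain as a hypothesis, as may a difference between the animals sampled.

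Among Paneth cell markers, the 11 members other than alpha-defensins had a median of -0.957 (8 fell, 1 rose), the 6 alpha-defensins one of -0.893, and Mmp7 rose by 0.5 on the log2 scale.

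In limma without the block the real grouping of the 6 libraries called 43 genes, 1 of 10 splits, and the highest of the others called 0. With the block it called 6040, 1 of the 4 splits that part every pair, and the highest of the others called 0. The splits are too few for a share under 0.05. Each of the others puts LPS and control libraries on both sides, so a real difference between the groups would widen its residual spread. Their 0 calls therefore do not show what a grouping without any effect would give.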
